A study of Mus musculus with 39 samples.

How the data were processed

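Lung RNA of mice was hybridised to Agilent two-colour mouse arrays of the 4x44K format, 1 array per lung, in 8 groups of 4 doses and 2 days. Per the labels' protocols, 200 ng of RNA with an integrity number above 7 was used per array, taken from random sections of lung, and the particles were instilled once in 40 µl. Per the labels the lung RNA carried Cy5, read in the red channel, and a universal mouse reference of 11 cell lines carried Cy3, read in the green channel. No dyes were swapped, so a dye effect cancels between groups. Lower doses, later days and other organs that the labels mention were not analysed here.

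Per the file headers, the scanner files were written by Agilent Feature Extraction 11.0.1.1 and hold median intensity of each spot and of its local background in both channels, with no normalization. The deposited files also hold a log10 ratio of red over green that the same software computed after its own background subtraction and dye normalization. The deposited value table of the series holds log2 ratios of sample over reference by the authors, whose method is not given in the sources used here. Its scale and direction were found by setting each column against the scanner log10 ratios over 3966 probes, which gave slopes of 3.13 to 3.23 and r of 0.958 to 0.996 for 36 samples, with 0.719 as the highest r to the column of another sample. The column medians lay between -0.049 and -0.023. How the authors centred the columns stays unknown. The table had 0 columns that belong to no sample.

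For samples 19, 20 and 21 the scanner file and the value column did not match, and these 3 arrays were left out. No file was moved to another sample by its values. Local background above 2 times the median of its array was reset to that median, which concerned 483 spots on 17 arrays and at most 228 on 1 array. Without this reset a few smeared spots made the background model compress arrays 4 and 30, whose log2 ratios had an SD of 0.521 and 0.509 as read and 0.894 and 0.808 after. The limit of 2 was the only one tried. Both steps depart from the design fixed before the data were examined and were chosen after the first counts had been seen. Median signals were used where that design assumed mean signals, since the scanner files give medians.

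The background was corrected with normexp (offset 50) over all spots in limma 3.58.1 under R 4.3.3, and the ratios were normalized within each array by loess with weight 0 for control spots. The 1639 control spots and spots that the software marked as outliers were then left out, and the 10 spots of each of 245 probes were averaged. A probe was kept if it was well above background in the red channel on at least 4 arrays, which left 31335 of 41174 probes. Probes were named through their accession in a RefSeq table of the mouse assembly GRCm38.p6, in which 27479 probes (66.7%) matched 18749 symbols. The 13695 others kept the name in the file. The arrays were designed on build mm9, so no coordinates are given. Of several probes of a gene the one with the highest mean signal was used, and probes that lacked a value on more than 2 arrays were left out. Probes of a gene can disagree: with their mean in its place, 14 of the 245 named calls were lost. This left 23849 genes, 16263 of them with a symbol and 5811 with several probes.

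Groups follow the dose and day in the labels, and the sample numbers 1 to 39 are unique, so they pair no samples. The highest correlation of centred values between 2 arrays was 0.682, so each array was counted as a sample of its own. The labels speak of 5 samples per group without tying each to an animal of its own, so p-values measure the spread between these samples. The number of arrays limits the precision. All 36 arrays entered a single limma fit with dose and day as 1 factor of 8 groups, slide as a random block (duplicateCorrelation, 0.263) and 28 residual degrees of freedom. The least squares step of limma's lmFit was written out for speed, checked against lmFit on simulated data, and followed by limma's variance moderation. A call is an adjusted p under 0.05 (Benjamini-Hochberg over all genes of a comparison). The trend is linear over the order of the 4 doses. The 30 gene lists, 671 names of which 2 were not matched, were tested with limma's cameraPR at a preset correlation of 0.01, adjusted over 180 tests, with camera at an estimated correlation and fry beside it. Some genes stand in several lists, and lung itself expresses many of them.

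Genes were named by a rule fixed before the data were examined. In each comparison with the controls these were the 10 largest rises and 5 largest falls among called genes above background in both groups, up to 4 members of each list with the smallest adjusted p, and a panel of 28 genes, of which 27 were tested. In the other comparisons they were the 5 largest in each direction. The rule gives a gene that is well above background on no array of a group as a bound, and no gene given a value needed one. The difference of Mmp12 between days is left out, since no control array of day 1 had it well above background. The result of 1 further gene is not reported here.

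Alternatives covered the background correction, the normalization, the ratios of the scanner software, the authors' value table, the filter on dim probes, the probes of a gene, slide and scan day as blocks, the arrays in the fit, array weights, the variance model and leaving out each array. The procedure was tested on simulated data over 23764 genes. At 486 µg on day 1 it recovered 52%, 90%, 100% and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale and called 5 other genes. At 486 µg on day 28 it recovered 76%, 92%, 100% and 100% and called 11 others. The 1 raised list and 0 of 29 others were called, which left correlated genes untested.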

Results

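Whole-genome expression was measured in lungs of female C57BL/6 mice that had received a single intratracheal instillation of rutile titanium dioxide nanoparticles, 20 nm in diameter with a hydrophilic surface. The animals received 0, 54, 162 or 486 µg and were killed 1 or 28 days later. The 8 groups of dose and day held 39 two-colour microarrays on 11 slides, with lung RNA in the red channel and a universal mouse reference RNA in the green channel. Arrays carry the sample numbers 1 to 39. The comparisons used the 36 arrays whose scanner file matched the value column of the same sample. These were 4, 4, 5 and 4 lungs at 0, 54, 162 and 486 µg on day 1, and 5, 5, 4 and 5 lungs on day 28. Between 50.1% and 76.0% of the probes of a used array were well above background in the red channel. The labels state 5 samples for each group, and the p-values measure the spread between these samples.

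Each dose was compared with the control lungs of the same day. Changes are log2 differences of the sample-to-reference ratio, followed by the standard error of the fit after the sign ±, so that 1 unit is a doubling. Leaving out 3 arrays and resetting smeared local background were both chosen after the data were examined, first counts included. The count of each comparison is therefore also given with all 39 arrays, and with all 39 arrays and the local background as read, which was the design fixed before the data were examined. Under that design 147 of the 245 named calls were lost, and none changed direction. With slide as a fixed block 18 residual degrees of freedom are left in place of 28, so a call lost there is given with its estimate. Named values moved with the processing too: 47 of the 182 called values in the text changed by over 1.5 times under an alternative, most often with the ratios that the scanner software wrote, and these are given with each comparison. Calls ended by alternatives to the processing and the fit are given as the number, of 16 to 18, that ended them. A few named genes were well above background on only some arrays of a group. For Cxcl5 these were 1 of 4 control arrays at day 1 and 1 of 5 at day 28, and for Mmp12 1 of 5 control arrays at day 28, so the size of their rises is uncertain. At 54, 162 and 486 µg on day 28 Alb was so on 4 of 5, 3 of 4 and 3 of 5 arrays and Fgb on 2 of 5, 1 of 4 and 2 of 5, and Fgb on 1 of 4 control arrays at day 1. Tnf was so on 3 of 4 arrays at 486 µg on day 1.

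At day 1 and 54 µg the genes that rose included members of the serum amyloid A family and the neutrophil-attracting chemokine gene Cxcl5. Saa3, an acute phase protein of the serum amyloid A family, rose by 5.31 ± 0.75 (n = 4 against 4, adjusted p = 0.00130), a 39.8-fold higher signal. Saa1 of the same family rose by 2.41 ± 0.49, Lcn2, a siderophore-binding protein, by 2.62 ± 0.43, and Timp1, an inhibitor of matrix metalloproteinases, by 2.67 ± 0.52. Cxcl5 rose by 2.59 ± 0.44, Slc26a4, the anion exchanger pendrin, by 2.13 ± 0.40, and Ly6f, a member of the Ly6 family, by 1.55 ± 0.27. Noxo1, the organizer of NADPH oxidase 1, rose by 1.42 ± 0.23, complement component C3 by 1.26 ± 0.21, and the ferroxidase gene Cp by 1.08 ± 0.21. Each of these 10 genes was higher within both slides that held both groups. In all, 16 of 23849 genes were higher and 0 lower at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), with 2232 at an unadjusted p under 0.05 where chance gives 1192. The count was 16 with all 39 arrays, 3 under the design fixed before, 48 with slide as a fixed block, 1, 2 and 8 without arrays 1, 2 and 36, and 47 without array 14. With only the arrays of the day it was 2, and 1 of these was among the 16 reported. Cp lost its call with slide as a fixed block (adjusted p = 0.0527), at a similar 1.12 ± 0.24. With the scanner software's ratios, Cxcl5 stood at 5.28. Noxo1 and Saa3 lost their call in 1 alternative, C3 in 2, Cxcl5 and Lcn2 in 3, Ly6f in 4, Slc26a4 in 6, Cp in 7, Timp1 in 8, and Saa1 in 10. For Cp these were no slide block, slide or scan day as a fixed block, only the arrays of the day, all 39 arrays and the local background as read on 36 or 39 arrays, and for C3 the mean of all probes and the design fixed before. C3, Cxcl5, Lcn2 and Noxo1 lost their call without array 1 or 2 (adjusted p up to 0.134), and Cp without array 1, 2, 8, 28, 31 or 36 (adjusted p up to 0.581). Ly6f lost its call without array 1, 2 or 28 (adjusted p up to 0.0545), and Saa1 without array 1, 2, 8, 22, 28 or 36 (adjusted p up to 0.749). Slc26a4 lost its call without array 1, 2, 8 or 36 (adjusted p up to 0.381), and Timp1 without array 1, 2, 8, 22 or 36 (adjusted p up to 0.493).

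Gene lists fixed before the data were examined were tested as groups. Inflammatory chemokines shifted upwards (adjusted p = 1.1e-15, and adjusted p = 0.0125 with an estimated correlation), with 1 higher of 22 members and 15 higher and 1 lower when adjusted over the list alone. IL-1, TNF and IL-6 signalling genes shifted upwards (adjusted p = 4.6e-08, and adjusted p = 0.0117 with an estimated correlation), with 0 higher of 27 members and 5 higher over the list alone. Acute phase genes shifted upwards (adjusted p = 2.8e-10, and adjusted p = 0.0913 with an estimated correlation), with 4 higher of 21 members and 6 higher over the list alone. Cell cycle genes shifted upwards (adjusted p = 6.2e-12, and adjusted p = 0.252 with an estimated correlation), with 0 higher of 29 members and 8 higher over the list alone. A further 7 lists were called with the preset correlation only (adjusted p from 4.1e-04 to 0.0245). Type 2 response genes shifted upwards (adjusted p = 0.120 with an estimated correlation) with 1 member higher, and 5 higher and 1 lower over the list alone. Neutrophil markers, complement and cholesterol synthesis also shifted upwards (adjusted p = 0.239, 0.501 and 0.643 with an estimated correlation), with 0, 1 and 0 members higher and 1, 3 and 0 over the list alone. Endothelium markers, which turned upwards with scaling between arrays (adjusted p = 0.00553), and NK cell and erythroid markers shifted downwards (adjusted p = 0.472, 0.643 and 0.472 with an estimated correlation), with 0 members lower in each and 1, 0 and 0 over the list alone.

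At day 1 and 162 µg the genes that rose included the acute phase genes Saa1, Saa2 and Saa3, the chemokine genes Cxcl5 and Ccl7, the complement genes C3 and Cfb and the replication genes Mcm2 and Mcm6. Saa3 rose by 5.92 ± 0.69 (n = 5 against 4, adjusted p = 5.4e-06), Saa1 by 2.99 ± 0.45, Saa2 by 2.13 ± 0.37, Timp1 by 2.86 ± 0.47 and Lcn2 by 2.82 ± 0.39. The chemokine genes Cxcl5 and Ccl7, the latter an attractant of monocytes, rose by 2.56 ± 0.40 and 2.12 ± 0.37. Slc26a4 rose by 2.47 ± 0.36, Ly6f by 1.89 ± 0.24 and Noxo1 by 1.63 ± 0.21. Each of these 10 genes was higher within all 4 slides that held both groups and kept its call whichever array was left out. The largest falls were those of the clock gene Per1 (-1.09 ± 0.24), the transcription factor gene Klf4 (-0.99 ± 0.17), Errfi1, an inhibitor of the EGF receptor (-0.83 ± 0.22), the unnamed transcript AK088332 (-0.80 ± 0.17) and Gsn, which encodes gelsolin (-0.74 ± 0.12). In all, 297 genes were higher and 88 lower (limma, Benjamini-Hochberg), with 3122 at an unadjusted p under 0.05. The total of 385 was 253 with all 39 arrays, 107 under the design fixed before and 90 with only the arrays of the day. It was 158, 234 and 176 without the control arrays 2, 22 and 36, 166 and 225 without arrays 23 and 37, and 644 without array 3. AK088332 stood at -1.36 (call lost, adjusted p = 0.0608), Ccl7 at 3.38, Cxcl5 at 5.29 and Saa2 at 3.37 with the scanner software's ratios. AK088332 lost its call without array 23 (adjusted p = 0.0599), and Errfi1 without array 2, 3, 15, 30, 31 or 37 (adjusted p up to 0.320). Per1 lost its call without array 2 (adjusted p = 0.147).

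Inflammatory chemokines shifted upwards (adjusted p = 9.2e-20, and adjusted p = 0.00534 with an estimated correlation), with 13 higher of 22 members and 16 higher over the list alone. Ccl12 rose by 1.15 ± 0.19 and Ccl17, a ligand of the receptor CCR4, by 1.40 ± 0.28. IL-1, TNF and IL-6 signalling genes shifted upwards (adjusted p = 1.4e-11, and adjusted p = 0.00326 with an estimated correlation), with 8 higher of 27 members and 13 higher over the list alone. They included the feedback inhibitor Tnfaip3 (0.52 ± 0.10) and the receptor gene Tnfrsf1b (0.41 ± 0.08). Acute phase genes shifted upwards (adjusted p = 1.6e-12, and adjusted p = 0.0633 with an estimated correlation), with 7 higher of 21 members and 9 higher over the list alone. Cell cycle genes shifted upwards (adjusted p = 3.4e-21, and adjusted p = 0.0913 with an estimated correlation), with 6 higher of 29 members and 15 higher over the list alone. The replication helicase genes Mcm2 and Mcm6 rose by 0.86 ± 0.11 and 0.85 ± 0.10, and Pcna, the sliding clamp, by 0.59 ± 0.10. Interferon response genes shifted upwards (adjusted p = 2.3e-09, and adjusted p = 0.202 with an estimated correlation), with 1 higher of 28 members and 10 higher over the list alone. Neutrophil markers shifted upwards (adjusted p = 1.7e-07, and adjusted p = 0.0654 with an estimated correlation), with 1 higher of 21 members and 9 higher over the list alone. Complement genes shifted upwards (adjusted p = 5.5e-05, and adjusted p = 0.152 with an estimated correlation), with 3 higher of 19 members and 3 higher over the list alone. C3 rose by 1.44 ± 0.19 and Cfb, factor B of the alternative pathway, by 1.12 ± 0.16. Type 2 response, monocyte and cholesterol synthesis lists shifted upwards with 4, 1 and 0 members higher and 6, 4 and 2 over the list alone, and endothelium markers downwards with 0 and 1 lower. These 4 did not keep their call (adjusted p from 3.5e-04 to 0.0450, and adjusted p from 0.110 to 0.688 with an estimated correlation). The circadian clock list was not called (adjusted p = 0.617) and held 4 higher and 3 lower members, 5 and 4 over the list alone. Among them Nr1d1, a repressor of the clock, rose by 0.81 ± 0.17 and Arntl, its activator, stood lower (-0.63 ± 0.13). With the mean of all probes of a gene, Nr1d1 stood at 0.34 and Tnfrsf1b at 0.21 (call lost, adjusted p = 0.160). Gsn, Saa2, Slc26a4, Timp1 and Tnfaip3 lost their call in 1 alternative, Arntl, Cfb, Nr1d1 and Tnfrsf1b in 2, AK088332 and Ccl17 in 3, Per1 in 4, and Errfi1 in 9.

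At day 1 and 486 µg the genes that rose included the acute phase genes Saa1, Saa2 and Saa3, the chemokine genes Ccl2 and Ccl7 and the metallothionein gene Mt2, and array 9, 1 of the 4 lungs, lay near the controls for several of them. Saa3 rose by 6.19 ± 0.75 (n = 4 against 4, adjusted p = 3.6e-05), Saa1 by 3.10 ± 0.50, Saa2 by 2.54 ± 0.40, Timp1 by 3.57 ± 0.52 and Lcn2 by 2.77 ± 0.43. Ccl2, which attracts monocytes, rose by 2.56 ± 0.44, Mt2 by 2.50 ± 0.51, the cornified envelope gene Sprr1a by 2.68 ± 0.41, Pbp2 by 2.80 ± 0.38 and the unnamed transcript NAP109359-1 by 2.66 ± 0.34. The cytokine genes Il33 and Il1b rose by 1.29 ± 0.17 and 1.27 ± 0.30. Cxcl5, raised at both lower doses, stood at 0.65 ± 0.44 (adjusted p = 0.473). The largest falls were those of Krtap17-1, a keratin-associated protein gene (-1.53 ± 0.32), the proteoglycan gene Bcan (-1.52 ± 0.27), the apelin receptor gene Aplnr (-1.44 ± 0.30), Fabp1, a fatty acid-binding protein gene (-1.38 ± 0.41), and the fibulin gene Fbln1 (-1.23 ± 0.22). On array 9 Saa3 stood at -0.83, against -3.61 to -3.04 in the controls and 2.49 to 3.92 in the other 3 lungs at this dose. Ccl2 stood there at -4.41, against -4.46 to -3.78 and -1.23 to -0.79.

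In all, 678 genes were higher and 526 lower at day 1 and 486 µg (limma, Benjamini-Hochberg), with 4388 at an unadjusted p under 0.05. This count is fragile: the total of 1204 was 152 with all 39 arrays (114 higher and 38 lower), 26 under the design fixed before, 422 with the 36 arrays and the local background as read, and 1825 with slide as a fixed block. With only the arrays of the day the total was 163. It was 2725 without array 9, 493, 542 and 715 without arrays 16, 29 and 38, and 667 and 642 without the control arrays 2 and 22. Krtap17-1 stood at -2.79 with the scanner software's ratios. Aplnr stood at -0.81 with the mean of all probes of a gene. Under the design fixed before, Fabp1 stood at -0.91 (call lost, adjusted p = 0.726). Fabp1 lost its call without array 2, 16, 22, 29, 36 or 38 (adjusted p up to 0.187), and Il1b without array 29 (adjusted p = 0.0567).

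Acute phase genes shifted upwards (adjusted p = 1.4e-12, and adjusted p = 0.0633 with an estimated correlation), with 10 higher of 21 members and 11 higher over the list alone. Inflammatory chemokines shifted upwards (adjusted p = 6.4e-10, and adjusted p = 0.0654 with an estimated correlation), with 6 higher of 22 members and 12 higher over the list alone. Ccl7 rose by 2.37 ± 0.40 and Ccl12 by 1.24 ± 0.20. IL-1, TNF and IL-6 signalling genes shifted upwards (adjusted p = 6.3e-09, and adjusted p = 0.00707 with an estimated correlation), with 11 higher of 27 members and 15 higher and 2 lower over the list alone. The oncostatin M receptor gene Osmr rose by 0.68 ± 0.13 and Bcl3, an atypical IκB protein, by 0.68 ± 0.14. Cholesterol synthesis genes shifted upwards (adjusted p = 4.5e-08, and adjusted p = 0.110 with an estimated correlation), with 6 higher of 22 members and 10 higher over the list alone. Lanosterol synthase, Lss, rose by 0.79 ± 0.11. Neutrophil markers shifted upwards (adjusted p = 1.0e-07, and adjusted p = 0.0654 with an estimated correlation), with 6 higher of 21 members and 11 higher over the list alone. The receptor gene Trem1 rose by 0.49 ± 0.10. Endothelium markers shifted downwards (adjusted p = 1.2e-05, and adjusted p = 0.259 with an estimated correlation), with 3 lower of 22 members and 4 lower over the list alone. Among them Tie1, a receptor tyrosine kinase, stood lower (-0.50 ± 0.09). Circadian clock genes shifted upwards (adjusted p = 0.00363, and adjusted p = 0.136 with an estimated correlation), with 5 higher and 1 lower of 18 members and 7 higher and 1 lower over the list alone. Nr1d1 rose by 0.80 ± 0.18. Oxidative stress genes shifted upwards (adjusted p = 0.0160, and adjusted p = 0.501 with an estimated correlation), with 5 higher and 2 lower of 28 members and 6 higher and 2 lower over the list alone. Srxn1, which reduces peroxiredoxins, rose by 0.40 ± 0.09 and the aldo-keto reductase gene Akr1b8 by 0.93 ± 0.17. With the scanner software's ratios, Ccl7 stood at 3.65 and Tie1 at -0.079 (call lost, adjusted p = 0.909). Nr1d1 stood at 0.36 and Osmr at 0.44 with the mean of all probes of a gene. With scaling between arrays, Tie1 stood at -0.31 (call lost, adjusted p = 0.278).

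Extracellular matrix genes shifted upwards (adjusted p = 0.00973, and adjusted p = 0.512 with an estimated correlation), with 9 higher and 3 lower of 43 members and 15 higher and 8 lower over the list alone. Tnc, which encodes tenascin C, rose by 1.46 ± 0.28 and the stromelysin gene Mmp3 by 1.33 ± 0.27. The fibrillar collagen genes Col1a1 and Col3a1 stood at 0.13 ± 0.15 and -0.24 ± 0.20 (adjusted p = 0.742 and 0.605). Cell cycle, glucocorticoid and type 2 response lists shifted upwards (adjusted p = 0.759, 0.429 and 0.429 with an estimated correlation) with 2, 3 and 3 members higher and 5, 3 and 5 over the list alone, the last with 1 and 2 lower. Interferon response genes and NK cell markers shifted downwards, with 2 and 0 members lower and 3 and 0 over the list alone. None of these 5 kept its call (adjusted p from 0.00434 to 0.0322, and adjusted p from 0.429 to 0.759 with an estimated correlation). The median of the NK cell list was -0.25 in the fit, but -0.06 and 0.21 within the 2 slides that held both groups. Alveolar macrophage markers were not called as a list (adjusted p = 0.0670), with 3 members lower, and 2 higher and 4 lower over the list alone. Among them the cholesterol exporter gene Abcg1 stood lower (-1.12 ± 0.23). With the mean of all probes of a gene, Tnc stood at 0.88. Akr1b8, Ccl12, Ccl2, Ccl7, Lcn2, Lss, NAP109359-1, Nr1d1, Pbp2, Saa1, Saa2 and Sprr1a lost their call in 1 alternative, Abcg1, Bcan, Fbln1, Mmp3 and Osmr in 2, Bcl3, Il1b, Krtap17-1, Mt2 and Tnc in 3, Aplnr, Srxn1 and Trem1 in 4, Tie1 in 5, and Fabp1 in 12.

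**Figure D1:**
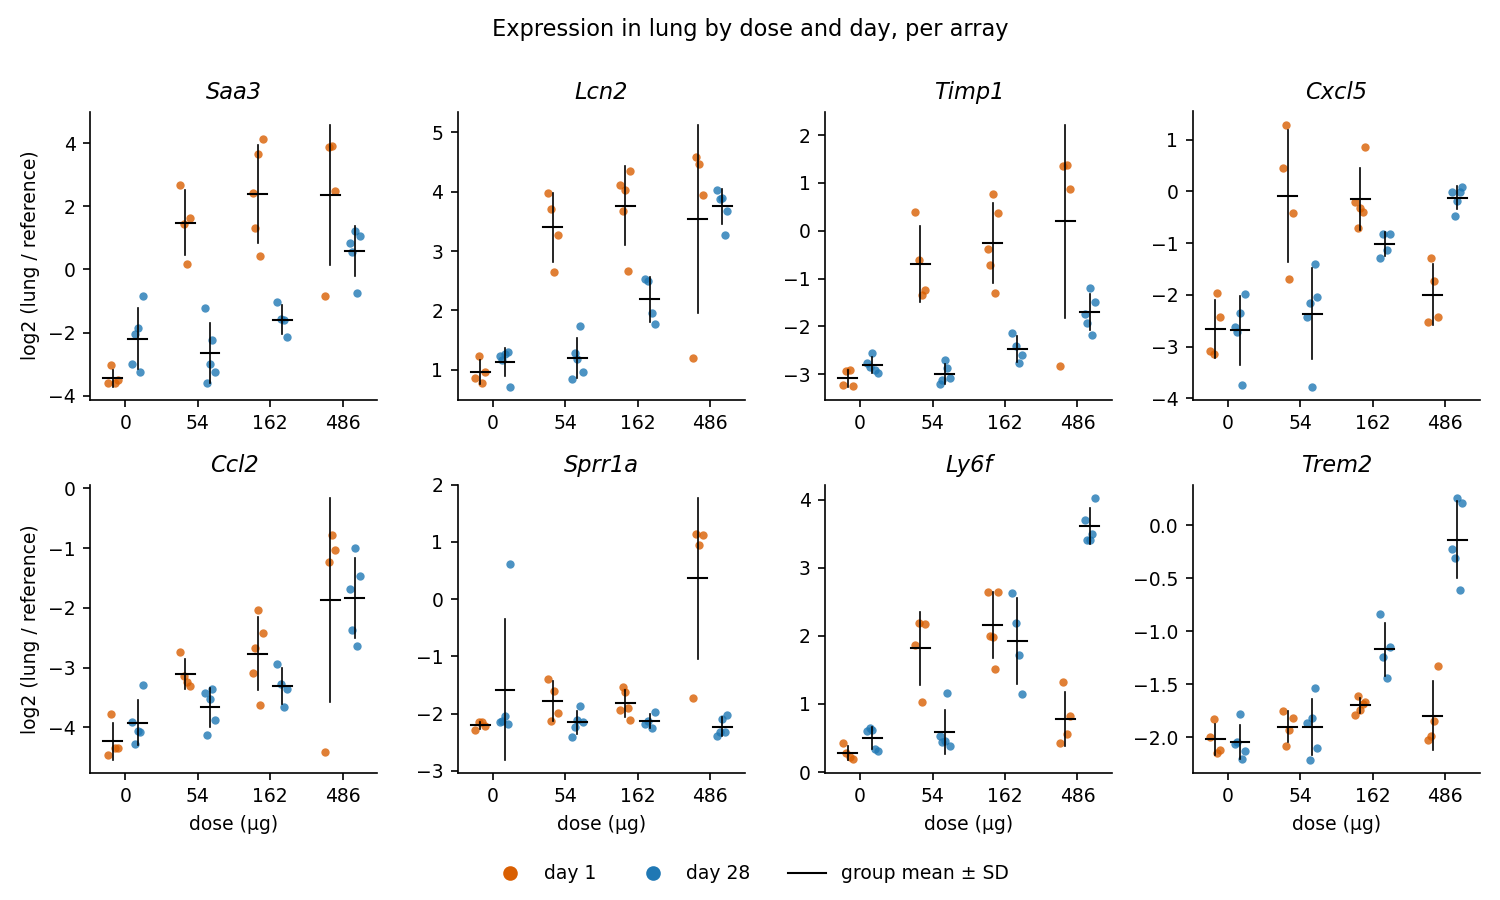
Log2 ratio of lung to reference RNA (vertical axis) for 8 genes by dose in µg (horizontal axis), with 1 point per array, day 1 in orange and day 28 in blue, and a line at each group mean with a bar of 1 SD on either side. The low orange point for Saa3 at 486 µg is array 9, at -0.83.

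At day 28, 54 µg left 0 genes higher, and the genes that were lower than in the control lungs included transcripts typical of liver. Alb, serum albumin, stood at -1.73 ± 0.26 (n = 5 against 5, adjusted p = 0.00544), the early response gene Nr4a1 at -1.54 ± 0.26 and the carboxylesterase gene Ces1c at -1.40 ± 0.24. Serpina1d, an antitrypsin gene, stood at -1.28 ± 0.23 and the fibrinogen gene Fgb at -1.11 ± 0.18. Saa3 and Lcn2 stood at -0.46 ± 0.65 and 0.05 ± 0.37 (adjusted p = 0.967 and 0.995). The liver transcripts were high in the control lungs of this day: Alb was 1.90 to 3.37 in 4 of the 5 and 0.46 in array 4, against 0.19 to 0.44 in the 4 control lungs of day 1. In all, 0 genes were higher and 6 lower (limma, Benjamini-Hochberg), with 1380 at an unadjusted p under 0.05. With slide as a fixed block the count was 0. It was 5 with all 39 arrays, 3 under the design fixed before, 1, 2 and 3 without arrays 26, 10 and 32, and 10 and 11 without the control arrays 4 and 33. Alb, Ces1c, Fgb, Nr4a1 and Serpina1d lost their call with slide as a fixed block (adjusted p from 0.110 to 0.435), with Alb at -1.58 ± 0.30, Ces1c at -1.41 ± 0.29, Fgb at -0.98 ± 0.20, Nr4a1 at -1.66 ± 0.27 and Serpina1d at -1.16 ± 0.27, changes about as large as reported. Fgb stood at -2.56 (call lost, adjusted p = 0.120) with the scanner software's ratios. Ces1c stood at -0.86 with the mean of all probes of a gene. Alb and Fgb lost their call in 3 alternatives, Ces1c and Serpina1d in 5, and Nr4a1 in 7. Ces1c lost its call without array 26 or 32 (adjusted p up to 0.0586), and Fgb and Nr4a1 without array 10 or 26 (adjusted p up to 0.102). Serpina1d lost its call without array 10, 12, 18, 26, 32 or 39 (adjusted p up to 0.116).

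At 162 µg on day 28 the phagocyte receptor gene Trem2 rose by 0.91 ± 0.14 (n = 4 against 5, adjusted p = 0.00184) and Ly6f by 1.41 ± 0.24. Lower were Alb (-1.87 ± 0.28), Nr4a1 (-1.58 ± 0.27), Serpina1d (-1.43 ± 0.24), Ces1c (-1.42 ± 0.25) and Fgb (-1.12 ± 0.19). Cxcl5 and Lcn2 stood at 1.69 ± 0.40 and 1.07 ± 0.39 (adjusted p = 0.160 and 0.793). In all, 2 genes were higher and 8 lower (limma, Benjamini-Hochberg), with 1298 at an unadjusted p under 0.05, and the split was 3 and 6 with the scanner software's ratios, 10 and 7 with only the arrays of the day, and 48 and 49 with array weights. With slide as a fixed block the total of 10 was 1. It was 15 with all 39 arrays, 5 under the design fixed before, 6 without array 5 or without array 13, and 19 without the control array 4. Alb, Ces1c, Fgb, Ly6f, Nr4a1 and Serpina1d lost their call with slide as a fixed block (adjusted p from 0.0562 to 0.116), with Alb at -1.76 ± 0.30, Ces1c at -1.41 ± 0.29, Fgb at -1.02 ± 0.20, Ly6f at 1.41 ± 0.28, Nr4a1 at -1.65 ± 0.27 and Serpina1d at -1.36 ± 0.27, changes about as large as reported. Fgb stood at -2.98 with the scanner software's ratios. Ces1c stood at -0.88 with the mean of all probes of a gene. Alb, Fgb and Trem2 lost their call in 2 alternatives, Nr4a1 and Serpina1d in 4, Ces1c in 5, and Ly6f in 6. For Ly6f these were the scanner software's ratios, slide as a fixed block, all 39 arrays, the local background as read on 36 or 39 arrays and the 39 columns of the value table, and for Trem2 the last and the design fixed before. Ces1c lost its call without array 35 (adjusted p = 0.0919), and Fgb without array 13 (adjusted p = 0.0729). Ly6f lost its call without array 5 or 13 (adjusted p up to 0.132), and Nr4a1 without array 5, 10 or 13 (adjusted p up to 0.0869).

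Liver markers stood lower at both of these doses. At 54 µg 2 of their 9 members were lower, and 6 were lower and 1 higher over the list alone (adjusted p = 2.3e-12, and adjusted p = 0.00369 with an estimated correlation). At 162 µg 2 were lower, and 6 over the list alone (adjusted p = 2.3e-12, and adjusted p = 0.00369 with an estimated correlation). Phagocyte lysosome and lipid handling genes shifted upwards (adjusted p = 8.6e-07, and adjusted p = 0.0654 with an estimated correlation), with 1 higher of 23 members and 4 higher over the list alone at 162 µg. Inflammatory chemokines shifted upwards (adjusted p = 4.5e-08, and adjusted p = 0.110 with an estimated correlation), with 0 higher of 22 members and 3 higher over the list alone at 162 µg. Dendritic cell, interferon response, type 2 response, T cell and IL-1, TNF and IL-6 lists shifted upwards at 162 µg (adjusted p from 0.180 to 0.650 with an estimated correlation) with 0 members called, and 0, 0, 1, 0 and 2 higher over the list alone. Skeletal muscle markers shifted downwards with 0 members lower on either count. None of these 6 kept its call (adjusted p from 1.0e-04 to 0.0450, and adjusted p from 0.180 to 0.650 with an estimated correlation). At 54 µg adipose, T cell, cardiac muscle, B cell and clock lists shifted upwards, and type I and type II epithelium, monocyte, endothelium and cholesterol synthesis lists downwards, with 0 members called and no call kept (adjusted p from 1.1e-11 to 0.0430, and adjusted p from 0.136 to 0.759 with an estimated correlation). The endothelium list turned upwards with the local background as read (adjusted p = 0.00222 with 36 arrays and 0.00215 with all 39). Adjusted over the list alone, 5 adipose markers were higher, 2 monocyte markers and 1 clock gene lower, and the other 7 lists held 0. Within the 4 slides that held both groups the median of the adipose list ranged from -0.25 to 3.33 and that of the cardiac list from -1.04 to 2.18. At 162 µg the skeletal muscle list ranged from -5.47 to 0.18, and was lower within 1 of the 4.

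**Figure D2:**
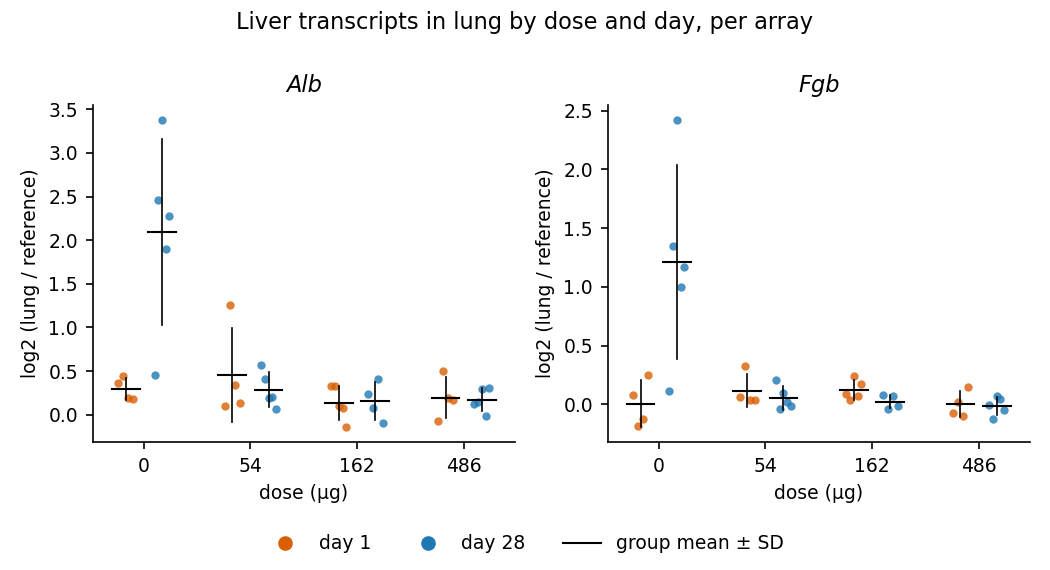
Log2 ratio of lung to reference RNA (vertical axis) for Alb (left) and Fgb (right) by dose in µg (horizontal axis), with 1 point per array, day 1 in orange and day 28 in blue, and a line at each group mean with a bar of 1 SD on either side. In 4 of the 5 control lungs of day 28 Alb lay between 1.90 and 3.37, and in array 4 at 0.46.

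At day 28 and 486 µg the interferon response, chemokine, phagocyte and monocyte lists shifted upwards and the list of alveolar macrophage markers did not pass the test. Ly6f rose by 3.11 ± 0.23 (n = 5 against 5, adjusted p = 7.7e-11), Saa3 by 2.78 ± 0.64, Slc26a4 by 2.71 ± 0.34 and Lcn2 by 2.62 ± 0.36. The chemokine genes Cxcl5, Ccl7, Ccl8 and Ccl2 rose by 2.56 ± 0.37, 2.31 ± 0.34, 2.22 ± 0.31 and 2.09 ± 0.37. Spp1, which encodes osteopontin, rose by 2.24 ± 0.29 and Noxo1 by 2.08 ± 0.19. Each of these 10 genes was higher within all 5 slides that held both groups. The largest falls were those of Alb (-1.92 ± 0.26), Cst8, a member of the cystatin family (-1.76 ± 0.26), Serpina1d (-1.51 ± 0.22), Ces1c (-1.29 ± 0.23) and Fgb (-1.22 ± 0.18). In all, 256 genes were higher and 60 lower (limma, Benjamini-Hochberg), with 2347 at an unadjusted p under 0.05. The total of 316 was 250 with all 39 arrays, 203 under the design fixed before and 195 without array 17, and array weights gave 812 higher and 509 lower. With the scanner software's ratios, Cxcl5 stood at 5.04, Fgb at -3.09 and Ly6f at 1.91. With the mean of all probes of a gene, Ces1c stood at -0.79. Saa3 lost its call without array 4, 17 or 25 (adjusted p up to 0.0730).

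Interferon response genes shifted upwards (adjusted p = 3.4e-38, and adjusted p = 0.00365 with an estimated correlation), with 15 higher of 28 members and 25 higher over the list alone. They included the oligoadenylate synthase genes Oas1a (1.03 ± 0.14), Oas2 (0.99 ± 0.15) and Oasl2 (0.96 ± 0.16) and the chemokine gene Cxcl10 (1.92 ± 0.28). Inflammatory chemokines shifted upwards (adjusted p = 6.0e-29, and adjusted p = 0.00171 with an estimated correlation), with 14 higher of 22 members and 16 higher over the list alone. Ccl4 rose by 1.68 ± 0.23, Ccl12 by 1.55 ± 0.17 and Ccl9 by 1.37 ± 0.19. Phagocyte lysosome and lipid handling genes shifted upwards (adjusted p = 1.7e-25, and adjusted p = 3.1e-04 with an estimated correlation), with 11 higher of 23 members and 14 higher over the list alone. Trem2 rose by 1.91 ± 0.13, Gpnmb, a glycoprotein of lysosome-rich macrophages, by 1.47 ± 0.16 and the lysosomal protease gene Ctsk by 1.29 ± 0.22. Monocyte and interstitial macrophage markers shifted upwards (adjusted p = 1.4e-12, and adjusted p = 0.0140 with an estimated correlation), with 5 higher of 22 members and 8 higher over the list alone. Ms4a7 rose by 1.65 ± 0.19 and the Fc receptor gene Fcgr1 by 1.03 ± 0.13. IL-1, TNF and IL-6 signalling genes shifted upwards (adjusted p = 3.0e-12, and adjusted p = 0.00285 with an estimated correlation), with 7 higher of 27 members and 12 higher over the list alone. Tnfaip3 rose by 0.73 ± 0.09 and Tnfrsf1b by 0.53 ± 0.08. Alveolar macrophage markers were not called (adjusted p = 0.617), with a median of -0.12 7 of 19 members above 0, 1 higher and 1 lower, and 2 higher and 1 lower over the list alone. Liver markers shifted downwards (adjusted p = 3.4e-11, and adjusted p = 0.00562 with an estimated correlation), with 4 lower of 9 members and 6 lower over the list alone. Within the 5 slides that held both groups the median of the interferon list ranged from 0.23 to 1.41 and that of the chemokine list from 0.75 to 1.37. Cxcl10 stood at 2.90 with the scanner software's ratios. Tnfrsf1b stood at 0.24 (call lost, adjusted p = 0.0942) with the mean of all probes of a gene.

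T cell markers shifted upwards (adjusted p = 4.4e-09, and adjusted p = 0.0645 with an estimated correlation), with 3 higher of 21 members and 9 higher over the list alone at day 28 and 486 µg. The costimulator gene Icos rose (adjusted p = 3.3e-05), as did Cd6, by 0.79 ± 0.13. Complement genes shifted upwards (adjusted p = 8.8e-07, and adjusted p = 0.0860 with an estimated correlation), with 3 higher of 19 members and 5 higher over the list alone. C3 rose by 0.93 ± 0.18 and Cfb by 0.79 ± 0.14. Dendritic cell and MHC class II genes shifted upwards (adjusted p = 8.3e-05, and adjusted p = 0.180 with an estimated correlation), with 2 higher of 19 members and 6 higher over the list alone. The costimulator gene Cd86 rose by 0.51 ± 0.08. Type I alveolar epithelium markers shifted downwards (adjusted p = 5.0e-05, and adjusted p = 0.136 with an estimated correlation), with 1 lower of 15 members and 1 lower over the list alone. Endothelium markers shifted downwards (adjusted p = 4.3e-07, and adjusted p = 0.180 with an estimated correlation), with 0 lower of 22 members and 0 lower over the list alone. NK cell, neutrophil, type 2 and acute phase lists shifted upwards (adjusted p from 0.236 to 0.643 with an estimated correlation) with 1, 1, 2 and 2 members higher and 2, 7, 2 and 6 over the list alone, the last with 1 lower on either count. Cell cycle and cholesterol synthesis lists shifted upwards, and skeletal muscle and erythroid lists downwards, with 0 members called on either count. None of these 8 kept its call (adjusted p from 1.1e-06 to 0.0245, and adjusted p from 0.236 to 0.771 with an estimated correlation). The skeletal muscle median was lower within 1 of the 5 slides that held both groups, with a range from -5.48 to 0.35, so its fall rests on that slide. The series title speaks of changes of a fibrotic kind, and the extracellular matrix and fibrosis list was not called at this dose and day (adjusted p = 0.538, median -0.03, mean 0.09). Of its 43 members 2 were higher, and 6 over the list alone, among them the macrophage elastase gene Mmp12, near background in the control lungs (0.78 ± 0.09). Col1a1 and Col3a1 stood at 0.06 ± 0.13 and 0.10 ± 0.17 (adjusted p = 0.952 and 0.932). Cd86 stood at 1.17 and Mmp12 at 2.99 with the scanner software's ratios. C3 stood at 0.59 (call lost, adjusted p = 0.0668), Cd6 at 0.44 and Icos at 0.72 with the mean of all probes of a gene. Ces1c, Cfb and Icos lost their call in 1 alternative, Saa3 in 2, and Cst8 in 3.

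Of the 180 list tests, 30 lists in 6 comparisons, 75 were called with the preset correlation, 55 upwards and 20 downwards, and 13 of these with an estimated correlation. Of the 75, 72 had a median over slides in the same direction, and 50 had it within every slide that held both groups. The lists of p53 targets, of club and ciliated airway epithelium markers and of alveolar macrophage markers were called in none, with a lowest adjusted p of 0.362, 0.316 and 0.0670.

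**Figure D3:**
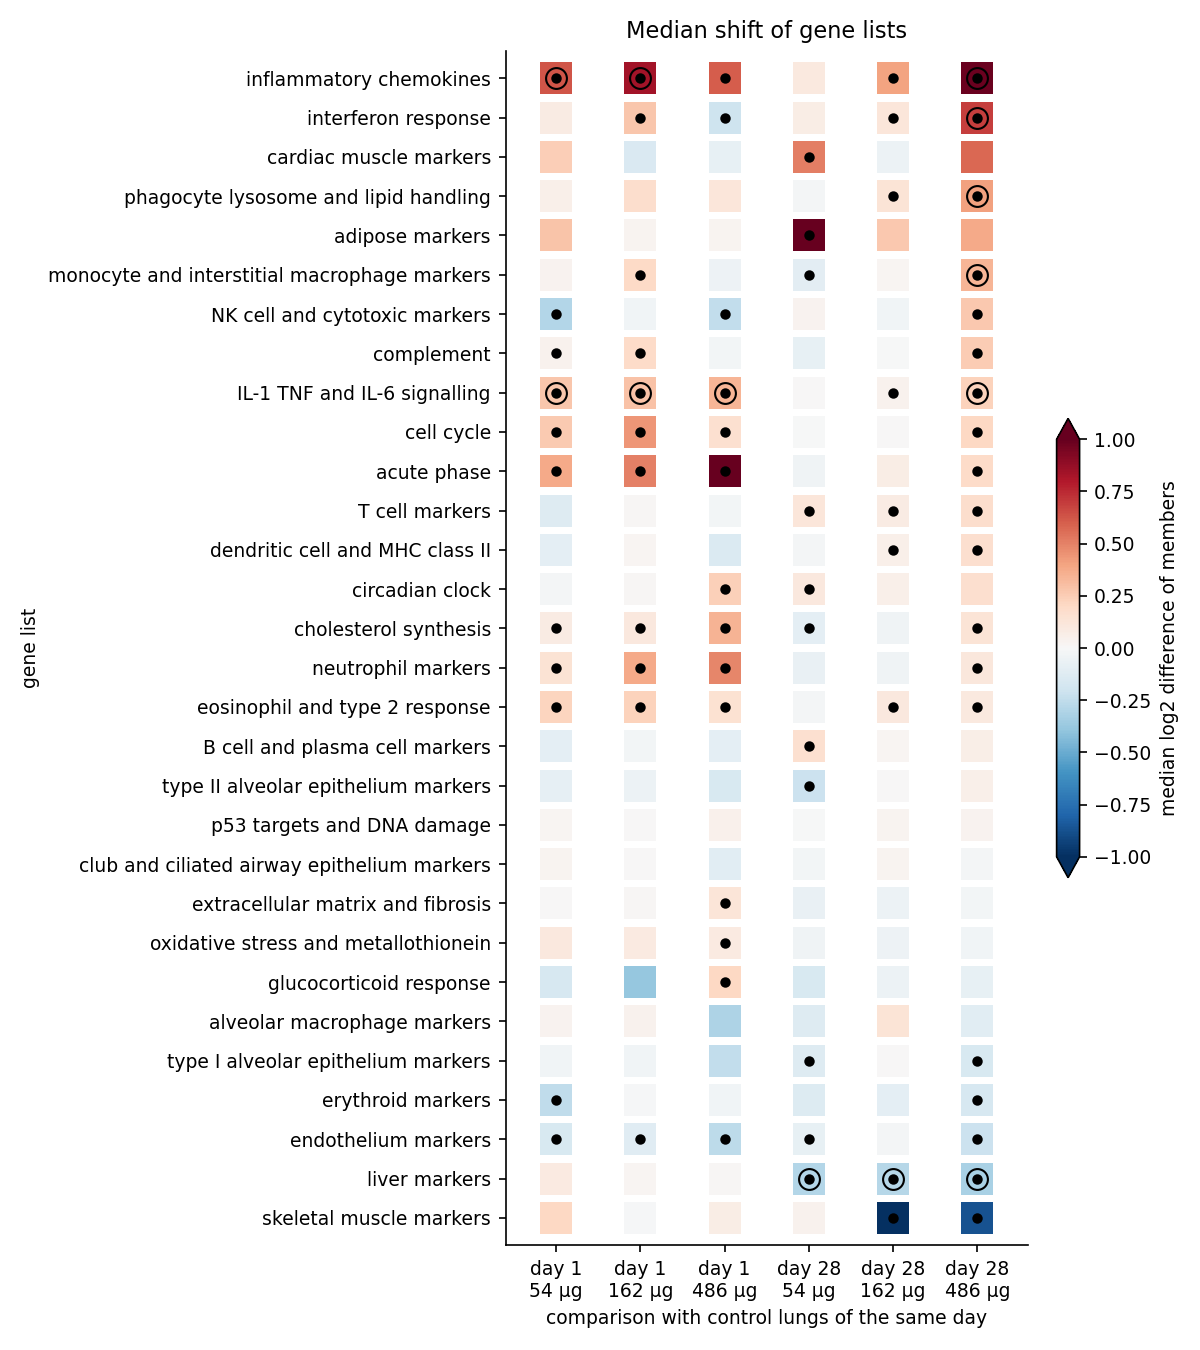
Median log2 difference from the control lungs of the same day over the measured members of each of the 30 gene lists (vertical axis) in the 6 comparisons (horizontal axis). Colour gives the median and ends at 1 and -1, a filled dot a call with the preset correlation and a ring around it a call with an estimated correlation too, and the interferon list at day 28 and 486 µg stands at 0.69.

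The dose trend, the change in log2 signal per step over the 4 doses, was called for 619 rising and 448 falling genes at day 1, and for 284 and 77 at day 28 (limma, Benjamini-Hochberg). At day 1 the steepest rises were those of Saa3 (1.92 ± 0.23), Timp1 (1.09 ± 0.16), Saa1 (0.99 ± 0.15), Pbp2 (0.87 ± 0.12) and Lcn2 (0.85 ± 0.13). Saa3, Saa1, Timp1 and Lcn2 had most of their rise at the lowest dose already. Krtap17-1 (-0.45 ± 0.10), Bcan (-0.44 ± 0.08), Aplnr (-0.43 ± 0.09), Fbln1 (-0.40 ± 0.07) and Scube2 (-0.36 ± 0.07) fell most. At day 28 Ly6f (1.07 ± 0.07), Slc26a4 (0.96 ± 0.11), Saa3 (0.94 ± 0.20), Cxcl5 (0.91 ± 0.12) and Lcn2 (0.89 ± 0.12) rose most. Alb (-0.59 ± 0.08), Cst8 (-0.57 ± 0.08), Serpina1d (-0.47 ± 0.07), Ces1c (-0.39 ± 0.07) and Fgb (-0.37 ± 0.06) fell most. These genes other than Cst8 stood about as low at each dose, Alb at -1.73, -1.87 and -1.92, so their slopes come mostly from the control lungs of day 28, 4 of 5 of which held high liver transcripts. The day 1 total of 1067 was 127 with all 39 arrays, 10 under the design fixed before, 2507 without array 9, 525 and 514 without arrays 16 and 29, and 680 and 622 without the control arrays 2 and 22. The day 28 total of 361 was 266 with all 39 arrays, 198 under the design fixed before and 230 without array 17, and array weights gave 767 rising and 397 falling. With the scanner software's ratios, Krtap17-1 stood at -0.82 at day 1, and Cxcl5 at 1.76 and Fgb at -0.97 at day 28. With the mean of all probes of a gene, Aplnr stood at -0.23 at day 1 and Ces1c at -0.24 at day 28. Lcn2, Pbp2, Saa1 and Timp1 in the day 1 trend lost their call in 1 alternative, Bcan and Fbln1 in 2, Krtap17-1 and Scube2 in 3, and Aplnr in 4. At day 28 Ces1c and Saa3 lost theirs in 2, and Cst8 in 3.

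Between the 2 highest doses, 573 genes were higher and 581 lower at 486 than at 162 µg at day 1, and 41 higher and 1 lower at day 28 (limma, Benjamini-Hochberg). At day 1 Sprr1a (2.33 ± 0.38), Mt2 (2.02 ± 0.48), Pbp2 (2.00 ± 0.36), F3, which encodes tissue factor (1.73 ± 0.28), and Per1 (1.57 ± 0.25) were higher at 486 µg. Cxcl5 (-1.92 ± 0.41), Pisd-ps3 (-1.52 ± 0.42), Ly6f (-1.35 ± 0.25), the interferon-induced gene Ifi27l2a (-1.17 ± 0.32) and the guanylate-binding protein gene Gbp3 (-1.16 ± 0.22) were lower. At day 28 Ly6f (1.70 ± 0.24), Acod1, which makes itaconate (1.49 ± 0.25), Cxcl10 (1.40 ± 0.30), the transcript L38281 (1.32 ± 0.24) and Wfdc17 (1.32 ± 0.27) were higher, and Dync1li2 (-0.36 ± 0.07) lower. L38281, an unmatched name, had nearly the values of Acod1 at 486 µg, so both may be 1 gene. The day 1 total of 1154 was 235 with all 39 arrays, 115 under the design fixed before, 2740 without array 9, 380, 751 and 472 without arrays 16, 29 and 38, and 731 and 712 without arrays 15 and 37. The day 28 total of 42 was 98 with all 39 arrays, 56 under the design fixed before, 13 with slide as a fixed block, 26, 27 and 15 without arrays 11, 17 and 34, and 20, 11 and 7 without arrays 13, 27 and 35. Pisd-ps3 at day 1 lost its call with slide as a fixed block (adjusted p = 0.0629), at a similar -1.55 ± 0.49. Cxcl10, Dync1li2 and Wfdc17 at day 28 lost their call with slide as a fixed block (adjusted p from 0.103 to 0.120), with Cxcl10 at 1.29 ± 0.28, Dync1li2 at -0.35 ± 0.076 and Wfdc17 at 1.25 ± 0.28, changes about as large as reported. Ly6f at day 28 stood at 0.31 (call lost, adjusted p = 0.999) with the scanner software's ratios. Pisd-ps3 at day 1 stood at -0.92 and Dync1li2 at day 28 at -0.18 (call lost, adjusted p = 0.559) with the mean of all probes of a gene. Cxcl5 and Sprr1a at day 1 lost their call in 1 alternative, Ly6f in 2, Gbp3 and Pbp2 in 3, Mt2 in 4, and Ifi27l2a and Pisd-ps3 in 7. Acod1 at day 28 lost its call in 2 alternatives, L38281 in 3, Cxcl10 and Wfdc17 in 6, and Dync1li2 in 10. Ifi27l2a at day 1 lost its call without array 15, 16, 29, 30, 37 or 38 (adjusted p up to 0.138), and Mt2 without array 16 or 29 (adjusted p up to 0.107). Pisd-ps3 at day 1 lost its call without array 3, 15, 16, 29, 30, 37 or 38 (adjusted p up to 0.183). Cxcl10 at day 28 lost its call without array 11, 13, 17, 27, 34 or 35 (adjusted p up to 0.228), and Dync1li2 without array 11, 17, 27, 34 or 35 (adjusted p up to 0.286). L38281 at day 28 lost its call without array 27, 34 or 35 (adjusted p up to 0.0738), and Wfdc17 without array 5, 7, 11, 13, 17, 27 or 35 (adjusted p up to 0.239).

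**Figure D4:**
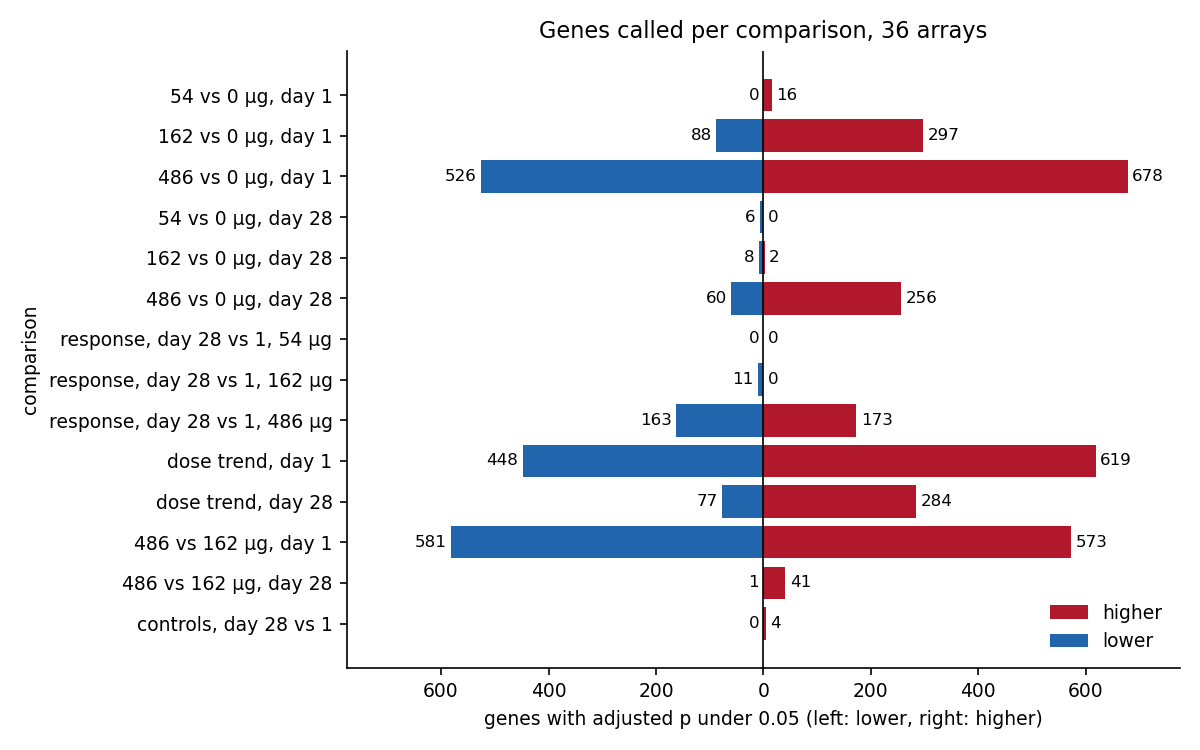
Number of genes higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in each of the 14 comparisons, on a linear axis. At day 28 the bars at 486 µg stand at 256 and 60.

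The days were compared through the difference of the changes from each day's own control lungs, which the days do not share. At 486 µg the change was more positive at day 28 than at day 1 for 173 genes and more negative for 163 (limma, Benjamini-Hochberg). The sign of this difference does not give the day with the larger change. The change was more positive at day 28 for Ly6f (2.56 ± 0.35), Ifi27l2a (2.34 ± 0.45), the transcript AK010014 (2.23 ± 0.42), Ms4a7 (1.69 ± 0.29) and Trem2 (1.64 ± 0.20). Sprr1a (-3.33 ± 0.54), Pbp2 (-2.67 ± 0.50), Mt2 (-2.60 ± 0.67), the fibrinogen gene Fgg (-2.21 ± 0.37) and S100a14 (-2.12 ± 0.46) had it at day 1. At 162 µg the change was more positive at day 28 for 0 genes and more negative for 11, with 1898 at an unadjusted p under 0.05. They included Saa3 (-5.27 ± 0.97), Ccno (-1.31 ± 0.21) and the replication genes Gins1 (-0.96 ± 0.18), Mcm2 (-0.95 ± 0.16) and Lig1 (-0.84 ± 0.12). At 54 µg 0 genes passed the test, with 1580 at an unadjusted p under 0.05, and the count was 6, 3 and 2 without arrays 4, 6 and 14. Of the genes called at 486 µg on both days 42 were higher on both, against 7.28 for independent lists, 5 were lower on both and 3 went opposite ways. Genes are not independent replicates, which limits this count and the correlation of the changes of the days (r = 0.188).

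The 486 µg total of 336 between days was 53 with all 39 arrays, 27 under the design fixed before, 548 with slide as a fixed block, 1501 without array 9, 126 and 140 without arrays 16 and 29, 209, 160, 202 and 189 without the control arrays 2, 22, 10 and 33, and 213 without array 11. The 162 µg total of 11 was 13 with all 39 arrays, 2 under the design fixed before, 0 with scaling between arrays, 1 with the local background as read on 36 arrays, 2 with no slide block, 30 and 17 without arrays 3 and 30, 5 and 3 without the control arrays 2 and 36, 6 and 3 without arrays 23 and 37, and 3, 3 and 2 without arrays 5, 13 and 27. The 54 µg count was 0 with all 39 arrays and under the design fixed before. At 486 µg Fgg stood at -3.96 and Ly6f at 1.29 (call lost, adjusted p = 0.414) with the scanner software's ratios. Lig1 at 162 µg lost its call in 1 alternative, Ccno in 3, Mcm2 in 4, and Gins1 and Saa3 in 6. Fgg at 486 µg lost its call in 1 alternative, Pbp2 in 2, S100a14 in 4, and Mt2 in 10. Gins1 at 162 µg lost its call without array 2, 4, 5, 13, 22, 23, 27, 33, 36 or 37 (adjusted p up to 0.107), and Mcm2 without array 27 (adjusted p = 0.0563). Saa3 at 162 µg lost its call without array 2, 5, 13, 23, 27, 35, 36 or 37 (adjusted p up to 0.0770). Mt2 at 486 µg lost its call without array 2, 4, 7, 10, 11, 16, 17, 22, 24, 29, 31, 33, 34, 36 or 38 (adjusted p up to 0.144), and S100a14 without array 29 (adjusted p = 0.0540).

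Control lungs of day 28 and day 1, which shared no slide, differed in 4 genes that are typical of liver and were higher at day 28: Alb (1.73 ± 0.31), Serpina1d (1.59 ± 0.27), Fgb (1.18 ± 0.22) and Ambp, the last named after its values were seen (limma, Benjamini-Hochberg, with 864 genes at an unadjusted p under 0.05). With slide as a fixed block, only array 39 (54 µg, day 28) shares a slide with day 1, so that fit cannot decide. The count was 0 with the local background as read on 36 arrays, with scaling between arrays and with probes well above background on all arrays. It was 5 with all 39 arrays, 3 under the design fixed before, 1 with the scanner software's ratios, 2 with scan day as a fixed block, 14 with array weights, 0 without any of the arrays 2, 10, 18, 22, 25, 31 or 36, and 9 without array 4. Alb stood at 1.43, Fgb at 0.80 and Serpina1d at 1.16 with slide as a fixed block. With the scanner software's ratios, Fgb stood at 2.97 (call lost, adjusted p = 0.172). Serpina1d lost its call in 4 alternatives, and Alb and Fgb in 5, slide as a fixed block included. Alb and Fgb lost their call without array 2, 10, 18, 22, 25, 31, 33 or 36 (adjusted p up to 0.189), and Serpina1d without array 2, 10, 18, 22, 25, 31 or 36 (adjusted p up to 0.150).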

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

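The counts of other splits and the tests that weigh explanations in this part were chosen only after the results were seen.

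Among 313 pairs of a named gene and a group, 33 held 1 array whose gap to the nearest other made up most of the range of the group, by Dixon's test, 10.5% of them, where chance gives about 1 in 20. Values are log2 ratios to the reference, with those of the other arrays of the group in brackets. Array 9, 486 µg at day 1, had Ccl12 at 0.15 (0.97 to 1.07), Ccl2 at -4.41 (-1.23 to -0.79), Fabp1 at 5.64 (2.70 to 2.91) and Krtap17-1 at 1.94 (0.99 to 1.15). It also had NAP109359-1 at -1.82 (0.43 to 0.87), Pbp2 at -0.065 (3.16 to 3.52), S100a14 at 2.81 (4.31 to 4.42) and Sema3e at 2.28 (0.93 to 1.15). It also had Sprr1a at -1.73 (0.94 to 1.15) and Timp1 at -2.82 (0.87 to 1.37). Array 33, 0 µg at day 28, had Krt79 at 2.73 (3.62 to 3.87), Lcn2 at 0.72 (1.17 to 1.29), Mt2 at -1.03 (-3.56 to -3.51) and Noxo1 at 0.22 (0.57 to 0.63). It also had S100a14 at 5.13 (2.83 to 3.12) and Sprr1a at 0.61 (-2.19 to -2.04). Array 24, 486 µg at day 28, had Acod1 at -3.21 (-1.80 to -1.30), Ces1c at 0.99 (0.66 to 0.69) and L38281 at -3.20 (-1.74 to -1.25). Array 22, 0 µg at day 1, had Ccl2 at -3.78 (-4.46 to -4.35) and Saa3 at -3.04 (-3.61 to -3.52). Array 23, 162 µg at day 1, had Gsn at 3.14 (3.77 to 3.83) and Pisd-ps3 at 2.66 (3.64 to 3.91). Array 30, 162 µg at day 1, had Bcan at 2.44 (0.86 to 1.30) and Slc26a4 at 3.09 (4.50 to 5.00). Array 2, 0 µg at day 1, had AK088332 at 0.66 (1.17 to 1.27). Array 16, 486 µg at day 1, had Fbln1 at -0.078 (-1.06 to -0.97). Array 38, 486 µg at day 1, had Aplnr at 2.55 (1.55 to 1.71). Array 18, 0 µg at day 28, had Oas2 at 0.30 (-0.20 to -0.083). Array 17, 486 µg at day 28, had Ccl8 at 4.01 (2.36 to 2.52). Array 6, 54 µg at day 28, had Serpina1d at 1.27 (0.11 to 0.30). Array 26, 54 µg at day 28, had Nr4a1 at -1.50 (-0.90 to -0.66). Array 32, 54 µg at day 28, had Ly6f at 1.16 (0.38 to 0.53).

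The test of the difference between the days' responses to the same dose, fixed before the data were examined, passed for the following named genes, given as log2 differences of day 28 minus day 1 (adjusted p from 3.3e-05 to 0.0474, limma). At 162 µg, the change was more negative at day 28 than at day 1 for Ccno (-1.31), Gins1 (-0.97), Lig1 (-0.84), Mcm2 (-0.95), Mcm6 (-0.79) and Saa3 (-5.27). At 486 µg, the change was more positive at day 28 than at day 1 for AK010014 (2.23), Fbln1 (1.37), Fcgr1 (1.09), Gbp3 (1.55), Gpnmb (1.05) and Icos (1.13). The same held for Ifi27l2a (2.34), Ly6f (2.56), Ms4a7 (1.69), Noxo1 (1.46), Oas1a (1.28) and Oas2 (1.59). The same held for Oasl2 (1.17) and Trem2 (1.64). At 486 µg, the change was more negative at day 28 than at day 1 for Alb (-1.77), Fgb (-1.21), Fgg (-2.21), Lss (-0.78), Mmp3 (-1.54) and Mt2 (-2.60). The same held for NAP109359-1 (-2.11), Pbp2 (-2.67), S100a14 (-2.12), Saa2 (-2.01), Serpina1d (-1.60) and Sprr1a (-3.33). Alb, Fgb and Serpina1d lay near the level of the day 1 control lungs at this dose on both days, so their differences come from the high liver signal of the day 28 control lungs. Mmp12 passed the test too, but it was not well above background on any control array of day 1, so no difference is given.

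Scanner files of the 3 arrays left out of the comparisons held signals above the control lungs of the day they are labelled with. Of 11 genes looked at, 3 lay above every control lung for array 19, 2 for array 20 and 10 for array 21. Saa3 lay 6.10 above the control mean in the file of array 21, labelled 54 µg at day 1, and 0.10 above it in the file of array 20, labelled 486 µg at day 1.

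Scanner files and value columns of samples 19, 20 and 21 did not match. The value column of sample 19 correlated best with the file attached to sample 20, and that of sample 20 with the file attached to sample 21, with r of 0.968 and 0.982, so files attached 1 place off may account for these 2. An exchange among the 3 alone is argued against, since the file of sample 19 correlated with column 21 at r = 0.0343 and with no column above 0.404. The column of sample 21 had no match above 0.659, and which sample the file of array 19 holds stays open. No biological explanation was tested.

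Liver transcripts were high in 4 of the 5 control lungs of day 28 and low on array 4. A slide effect is argued against at 486 µg, where 3 of the 9 liver markers were still called lower with slide as a fixed block, and the calls lost with it at 54 and 162 µg kept about their size, with Alb at -1.58 ± 0.30 and -1.76 ± 0.30 against -1.73 ± 0.26 and -1.87 ± 0.28. Liver RNA carried into these samples may be the source: array 4 was the lowest of the 5 for 5 of 7 listed liver markers other than Alb and Fgb, where chance gives 1 in 5 for each. The values of these markers had been seen when this test was chosen, so it leaves the explanation open. A difference in the control mice themselves would move the markers together too, stays open and was not tested.

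On array 9, a lung labelled 486 µg at day 1, Ccl2 lay at -4.41, within the range of the control lungs (-4.46 to -3.78), and Il1b at 2.61, above the other 3 lungs of the group (1.75 to 2.34). A control lung of day 1 with this label is argued against, since its Saa3 lay 2.21 above the highest control, whose range was 0.57. Flattened log ratios are argued against, since their SD was 0.883 against 0.778 to 0.979 on the other arrays of day 1. A smaller delivered dose stays open. Over the 16 genes called at 54 µg the lung's slope on their rise was 0.331 ± 0.058 (SE over genes). The 4 lungs at 54 µg had 0.568 to 1.44. Among the 16, Lcn2 and Cxcl5 lay in the control range, Timp1 and Ly6f just above, Saa3 2.21 above. Over the 2725 genes called without array 9 its slope on the other 3 lungs was -0.00310 and 1254 moved the same way. Another treated group's label was not tested.

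Other splits of the same arrays into groups of the same sizes, which ignore the slides, were refitted over the 23764 genes measured on every array, and splits with as many genes called were counted with the real split included. Chance is argued against with 1 of 35 splits for 54 µg at day 1 (16 genes, highest other 4), 1 of 100 splits for 162 µg at day 1 (384 genes, highest other 224), 1 of 100 splits for 486 µg at day 28 (313 genes, highest other 53) and 2 of 100 splits for the days at 162 µg (11 genes, highest other 24). The same holds with 1 of 100 splits for the trend at day 28 (358 genes, highest other 17). Chance stays open with 2 of 100 for the days at 486 µg (339 genes, highest other 395). So it does with 2 for the trend at day 1 (1059 genes, highest other 1548). It stays open at day 28 with 4 of 100 splits for 54 µg (6 genes, highest other 14). So it does with 2 for 162 µg (10 genes, highest other 18) and 1 for 486 against 162 µg (42 genes, highest other 35). There 0, 1 and 11 genes kept their call with slide as a fixed block, though named genes changed about as much. For the control lungs of the days it stays open with 4 splits (4 genes, highest other 15). Those lungs shared no slide, and leaving out any of 7 arrays gave 0 genes. The splits that called 14, 18 and 15 genes for 54 and 162 µg at day 28 and for the control lungs moved array 4, the control lung of day 28 with low Alb, to the other group. Chance cannot be excluded with 4 of 35 splits for 486 µg at day 1 (1197 genes, highest other 1762) and 7 of 100 splits for 486 against 162 µg at day 1 (1154 genes, highest other 2759). For the days at 54 µg the real split called 0 genes, so the count says nothing (highest other 4). For the days at 162 µg the count fell to 0 with scaling between arrays, so it depends on processing. The 3 other splits for 486 µg at day 1 that called as many genes each placed array 9 with control lungs, which points to a structure of the samples. At 486 against 162 µg the split that called 2759 genes exchanged array 9 with array 23. Those of 395 and 1548 genes moved array 9 too.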

How the results depend on the processing

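The reported setting, 36 arrays with smeared local background reset, was chosen after the first counts were seen, and all 39 arrays with local background as read is the design fixed before the data were examined. Of the alternatives, 4 were chosen after: all 39 arrays, local background as read on 36 arrays, all 39 columns of the value table, and scaling between arrays. No background correction, the value table of the 36 samples, no filter on dim probes and a robust variance trend left each of the 14 counts within 1.5 times the reported one. Aquantile left the log ratios as they were and tests nothing. Counts that moved by over 1.5 times are given here as totals, and the cause was not tested. With the ratios that the scanner software wrote they were 0 for 54 µg at day 28, 22 for the days at 162 µg, 198 for the days at 486 µg, 19 for 486 against 162 µg at day 28 and 1 for the control lungs of the days. With all 39 arrays they were 253 for 162 µg at day 1, 152 for 486 µg at day 1, 53 for the days at 486 µg, 127 for the trend at day 1, 235 for 486 against 162 µg at day 1 and 98 for 486 against 162 µg at day 28. With all 39 arrays and local background as read they were 3 for 54 µg at day 1, 107 for 162 µg at day 1, 26 for 486 µg at day 1, 3 for 54 µg at day 28, 5 for 162 µg at day 28 and 203 for 486 µg at day 28. Further counts there were 2 for the days at 162 µg, 27 for the days at 486 µg, 10 for the trend at day 1, 198 for the trend at day 28 and 115 for 486 against 162 µg at day 1. With array weights they were 31 for 54 µg at day 1, 1941 for 486 µg at day 1, 16 for 54 µg at day 28, 97 for 162 µg at day 28, 1321 for 486 µg at day 28, 5 for the days at 54 µg and 93 for the days at 162 µg. Further counts there were 1213 for the days at 486 µg, 1766 for the trend at day 1, 1164 for the trend at day 28, 1930 for 486 against 162 µg at day 1, 132 for 486 against 162 µg at day 28 and 14 for the control lungs of the days. With local background as read on 36 arrays they were 5 for 54 µg at day 1, 154 for 162 µg at day 1, 422 for 486 µg at day 1, 5 for 162 µg at day 28 and 1 for the days at 162 µg. Further counts there were 151 for the days at 486 µg, 450 for the trend at day 1, 406 for 486 against 162 µg at day 1, 9 for 486 against 162 µg at day 28 and 0 for the control lungs of the days. With the mean of all probes of a gene they were 10 for 54 µg at day 1 and 17 for the days at 162 µg. With no slide block they were 7 for 54 µg at day 1, 129 for 162 µg at day 1, 403 for 486 µg at day 1, 195 for 486 µg at day 28 and 2 for the days at 162 µg. Further counts there were 81 for the days at 486 µg, 387 for the trend at day 1, 203 for the trend at day 28, 360 for 486 against 162 µg at day 1 and 13 for 486 against 162 µg at day 28. With only the arrays of the day they were 2 for 54 µg at day 1, 90 for 162 µg at day 1, 163 for 486 µg at day 1, 139 for the trend at day 1 and 163 for 486 against 162 µg at day 1. Further counts there were 1 for 54 µg at day 28, 17 for 162 µg at day 28, 502 for 486 µg at day 28 and 70 for 486 against 162 µg at day 28. With scaling between arrays they were 189 for 162 µg at day 1, 639 for 486 µg at day 1, 0 for the days at 162 µg, 207 for the days at 486 µg, 589 for the trend at day 1 and 0 for the control lungs of the days. With scan date as a fixed block they were 8 for 54 µg at day 1, 249 for 162 µg at day 1, 601 for 486 µg at day 1, 7 for the days at 162 µg and 129 for the days at 486 µg. Further counts there were 605 for the trend at day 1, 455 for 486 against 162 µg at day 1, 21 for 486 against 162 µg at day 28 and 2 for the control lungs of the days. With slide as a fixed block they were 48 for 54 µg at day 1, 1825 for 486 µg at day 1, 0 for 54 µg at day 28, 1 for 162 µg at day 28, 548 for the days at 486 µg, 13 for 486 against 162 µg at day 28 and 12 for the control lungs of the days. With all 39 columns of the value table they were 31 for 54 µg at day 1, 767 for 486 µg at day 1, 1 for the days at 54 µg, 33 for the days at 162 µg, 158 for the days at 486 µg, 631 for 486 against 162 µg at day 1 and 79 for 486 against 162 µg at day 28. With probes well above background on all arrays they were 2 for 54 µg at day 28, 3 for 162 µg at day 28, 1 for the days at 54 µg, 25 for the days at 162 µg and 0 for the control lungs of the days. Of the 75 list shifts, 30 were called with fry. Endothelium markers turned upwards at 54 µg: at day 1 with scaling between arrays (adjusted p = 0.00553), at day 28 with all 39 arrays and local background as read (adjusted p = 0.00215) and with local background as read on 36 arrays (adjusted p = 0.00222). Leaving out 1 array at a time gave 1 to 47 for 54 µg at day 1, 0 to 6 for the days at 54 µg, 514 to 2507 for the trend at day 1, 158 to 644 for 162 µg at day 1, 493 to 2725 for 486 µg at day 1, 2 to 30 for the days at 162 µg, 126 to 1501 for the days at 486 µg and 0 to 9 for the control lungs of the days. It gave 380 to 2740 for 486 against 162 µg at day 1, 1 to 11 for 54 µg at day 28, 6 to 19 for 162 µg at day 28, 195 to 340 for 486 µg at day 28, 230 to 430 for the trend at day 28, 7 to 63 for 486 against 162 µg at day 28 and 70 to 80 for the list shifts. Of 245 calls of named genes none turned its direction under any setting. Calls lost were 147 with all 39 arrays and local background as read, 92 of 227 with only the arrays of the day, 89 with local background as read on 36 arrays, 80 with all 39 arrays, 69 with no slide block and 52 with scan date as a block. With each other setting 46 or fewer were lost, and 389 of 2500 with 1 array left out. Signal over background limits the reading of dim probes: 15138 genes had a probe well above background on all arrays.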

Other observations

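The interferon-induced gene Oas2 moved in opposite directions on the 2 days at 486 µg, and Gbp3 was lower at day 1. At day 1 Oas2 stood at -0.60 ± 0.18 and Gbp3 at -0.96 ± 0.24 against the control lungs (adjusted p = 0.0467 and 0.0151 from limma), and at day 28 Oas2 rose by 0.99 ± 0.15. The difference of its responses, singled out after its values were seen, was 1.59 ± 0.24 (adjusted p = 6.2e-04). Kdr, a receptor of VEGF on endothelium, was lower at -0.75 ± 0.17 at day 1 and 486 µg, as were Plvap, a protein of endothelial diaphragms, at -0.42 ± 0.12 and the semaphorin gene Sema3e at -0.60 ± 0.18. At day 28 Vegfa stood at -0.42 ± 0.08. Oas2 at day 1 lost its call with slide as a fixed block (adjusted p = 0.0686), at a similar -0.58 ± 0.19. Sema3e at day 1 stood at -0.37 (call lost, adjusted p = 0.0978) with the mean of all probes of a gene. It stood at -0.40 (call lost, adjusted p = 0.750) under the design fixed before. Kdr at day 1 stood at -0.30 (call lost, adjusted p = 0.686) and Plvap at day 1 at -0.065 (call lost, adjusted p = 0.953) with scaling between arrays. Gbp3 at day 1 lost its call in 6 alternatives, Kdr and Plvap in 9, Oas2 in 10, and Sema3e in 11. Vegfa at day 28 lost its call in 1 alternative. Gbp3 at day 1 lost its call without array 16, 22, 29 or 38 (adjusted p up to 0.0992), and Kdr without array 16 (adjusted p = 0.0557). Oas2 at day 1 lost its call without array 2, 16, 22, 29, 36 or 38 (adjusted p up to 0.206), and Plvap and Sema3e without array 2, 16, 22, 29, 31, 36 or 38 (adjusted p up to 0.217).

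The clock output gene Dbp rose by 1.13 ± 0.29 at day 1 and by 1.20 ± 0.25 at day 28 at 486 µg, and Arntl stood at -0.68 ± 0.12 at day 28. Csf1, the macrophage growth factor gene, rose by 0.37 ± 0.07 and 0.37 ± 0.06, and Tnf by 0.48 ± 0.11 and 0.43 ± 0.09. Krt79, a keratin gene listed here among alveolar macrophage markers, stood at -1.10 ± 0.23 at day 28. Tnf stood at 1.21 at day 1 and 0.95 at day 28 with the scanner software's ratios. Tnf at day 1 stood at 0.31 (call lost, adjusted p = 0.526) and Krt79 at day 28 at -0.60 (call lost, adjusted p = 0.756) under the design fixed before. With the local background as read on 36 arrays, Krt79 at day 28 stood at -0.60 (call lost, adjusted p = 0.682). Csf1 at day 1 lost its call in 3 alternatives, and Dbp and Tnf in 4. Arntl at day 28 lost its call in 1 alternative, and Krt79 and Tnf in 3. Dbp at day 1 lost its call without array 9, 22, 31, 36 or 38 (adjusted p up to 0.0785), and Tnf without array 38 (adjusted p = 0.0503). Tnf at day 28 lost its call without array 10 or 17 (adjusted p up to 0.0783). No hypothesis on these genes was tested.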
